A study of Mus musculus with 6 samples.

How the data were processed

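Gene expression was measured in undifferentiated mouse embryonic stem (ES) cells on 6 Affymetrix Mouse Gene 1.0 ST arrays, which carry many short probes per transcript and group them into probe sets. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The labels put 3 arrays in the parental wild-type line (WT) and 3 in a Hira-null clone made from ES cells, and number the arrays of each line 1 to 3 as biological replicates. The design text says that cells were collected at different degrees of confluence, and no label ties a degree of confluence to an array. The labels do not say whether the replicates of a line were separate cultures in any further sense, so p-values measure the spread between these arrays, which may be partly technical.

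The deposited table holds log2 expression values for 35557 probe sets, rounded to 2 decimals. The submitters' processing notes name GCRMA, a background correction and quantile normalization method for Affymetrix arrays, with no version. The log2 scale was read from the values, which run from 1.14 to 14.03. Array medians lie between 4.93 and 5.02, so the values deposited by the authors were already normalized between arrays and were used as they stand. A normalization of this kind equalises the overall distributions, so a change shared by most genes would not be seen. The genome build and annotation behind the authors' values are not given in the sources used here. Raw scanner signals and their background levels were not analysed here. The number of arrays limits the precision, with a median standard error of 0.17 for a log2 fold change.

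The platform's probe table named 23410 probe sets, of which 21789 carry 1 gene symbol and 1621 carry several. The other 12147 are unnamed here. Symbols were updated through Entrez identifiers with a gene table of the assembly GRCm38.p6, which matched 21698 of the 1-symbol probe sets. That table was used for current names, for the chromosome of a gene and for the order of genes, and no gene was named from a probe set with several symbols. A probe set was kept when at least 3 of the 6 arrays lay above 3.78, the 30th percentile of all values, which left 25142 probe sets. Of these, 16620 had 1 symbol and stood for 15199 genes. For gene lists and chromosomes each gene was represented by its probe set with the highest mean.

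The comparison was Hira-null minus WT, fitted over all 6 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The choices of groups, filter, tests, gene lists and named genes were made before the data were examined. Named genes are Hira and, in each direction, 12 genes with 1 symbol whose groups did not overlap, taken first from those past the threshold by size of change and then by smallest unadjusted p, leaving out predicted genes, clones, pseudogenes, small RNAs and large receptor families. From each gene list up to 4 members with the smallest unadjusted p were named, every measured member in lists of 8 or fewer genes, and Pou5f1, Nanog and Sox2 in any case. Genes named outside this rule are said to be so where they appear.

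There were 28 gene lists, chosen from general knowledge, covering the HIRA complex and other histone chaperones, histone genes, genes near Hira, pluripotency and lineage markers, germline, 2-cell-like, imprinted, Hox and Y-linked genes, Polycomb subunits, cell adhesion, proliferation, signalling targets, stress responses and metabolism. Of these, 27 had at least 4 measured genes and were tested with camera from limma with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were tested with camera using an estimated correlation and with fry. Each of 21 chromosomes was tested as a set in the same way. Chromosome medians per array are medians, over the genes of a chromosome, of the deviation from the gene's mean over the 6 arrays.

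The procedure was tested on simulated values for the same design. Of 200 probe sets given a log2 change of 1, 30.5% were called among 25230 tested, and of 200 given a change of 2, 89.5% were called among 25231 tested, with 3 and 9 wrong calls beside them. With no change, 0 of 25215 were called. With 15196 genes, 2 chromosomes (8 and 11) shifted by -0.25 were both called with 0 wrong calls, and 1 gene list (pluripotency) shifted by 0.50 was called. The simulated noise was independent between probe sets, whereas the estimated correlation within a gene list reached 0.80 in the data (cholesterol synthesis). These runs therefore do not measure wrong calls of lists or chromosomes among correlated genes. Alternatives tried were no filter and a stricter filter at the 50th percentile (4.99), quantile normalization and median centring of the deposited values, eBayes with a trend and with a trend and robust setting, arrayWeights, the replicate number as a block, leaving out each array in turn, the mean of a gene's probe sets, and a test against a change of 1.2-fold with treat. Added after the data were seen were fits without 2 arrays at the ends of principal components (WT replicate 1 and Hira-null replicate 3, although Hira-null replicate 1 was at the other end of component 2), with 1-symbol probe sets alone, and without the genes of chromosomes 8 and 11. Figures were drawn with matplotlib 3.10.9.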

Results

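Expression profiles were compared between a parental mouse ES cell line, w9.5, and the Hira-null ES cell clone Cl34, with 3 arrays for each line. HIRA is a histone chaperone that deposits the histone variant H3.3 outside DNA replication. The comparison asks how the transcriptome of undifferentiated ES cells differs between the parental line and this clone. The series holds 1 Hira-null clone, so effects of Hira loss cannot be told apart from other differences between the lines. This holds for every gene, list and chromosome below. Array medians were 4.93 to 5.02 on the log2 scale, and every value below is a deposited log2 value or a difference of such values, Hira-null minus WT, with SD over n = 3 arrays or the standard error (SE) from limma. The number of arrays limits the precision of every comparison. Principal component 1 held 41.7% of the variance and placed Hira-null replicate 3 at 65.6, against -32.0 to 1.95 for the other arrays. Principal component 2 held 26.8%, with the WT arrays at -40.7 to -5.12 and the Hira-null arrays at 2.19 to 42.7. WT replicate 1 and Hira-null replicate 1 were its ends.

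The Hira transcript was lower in the Hira-null arrays in all 3 replicates, without overlap between the lines. Its probe set (10434252, chromosome 16) read 7.49, 7.86 and 7.83 in WT and 7.40, 7.05 and 6.81 in Hira-null arrays. The means were 7.73 ± 0.21 and 7.09 ± 0.30, a log2 fold change of -0.64 (SE 0.19), or 1.56-fold lower. This did not pass the test over all probe sets (limma, adjusted p = 0.352) or adjusted over the list alone of HIRA complex genes (adjusted p = 0.0627). The labels do not say which part of the gene was deleted, so how far this probe set can check the genotype is not known. The other subunits and partners had values of 0.36 for Ubn1, 0.28 for Asf1a, 0.26 for Ubn2 and 0.03 for Cabin1, and none passed the test. The list of 5 HIRA complex genes did not pass as a set (median 0.26, adjusted p = 0.614). Among 18 measured neighbours of Hira on chromosome 16, the median was -0.02 and 0 passed with either adjustment. The neighbour with the smallest p was the tRNA methyltransferase Trmt2a, at -0.50, followed by Zdhhc8 at -0.21, Cdc45 at -0.26 and Ess2 at -0.15, and the set did not pass (adjusted p = 0.666).

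Dppa3, which encodes the maternal and germ cell factor Stella and marks naive pluripotent cells, was the gene called. Its probe set 10604135 averaged 6.08 ± 0.14 in WT and 3.77 ± 0.16 in Hira-null arrays, a log2 fold change of -2.30 (SE 0.14, limma adjusted p = 0.0217), or 4.94-fold lower, in 3 of 3 arrays. The other Dppa3 probe set, 10541515, fell short of the threshold at -1.94 (SE 0.15, adjusted p = 0.0526). A Dppa3 pseudogene is listed on chromosome X, and probe sequences were not examined, so signal from near-identical copies was not separated. The identifier 10604135 lies between those of the X-linked genes Efhc2 (10603768) and Usp26 (10604551). Which copy the called probe set reads is therefore not settled here. Of 25142 probe sets, 1 was called lower and 0 higher by limma, and treat gave the same 1 and 0. At an unadjusted p under 0.05 there were 2546 probe sets, 1022 higher and 1524 lower, where 1257 would arise by chance. A grouping of WT replicates 1 and 3 with Hira-null replicate 3 gave 2318, and the other groupings that mix the lines gave 337 to 1690. A grouping other than by line can thus come close to 2546, and the excess over 1257 cannot be read as a line difference alone. The lines did not overlap for 15.3% of probe sets, against 10% by chance. The Dppa3 call was lost when any array other than Hira-null replicate 2 was left out (adjusted p from 0.0685 to 0.313), with the replicate block (adjusted p = 0.493) and without WT replicate 1 and Hira-null replicate 3 together (adjusted p = 0.352), while its log2 fold change stayed between -2.38 and -2.22 over all alternatives. Without Hira-null replicate 2 there were 41 called probe sets, all lower, of which 19 belong to the Y-linked multicopy gene Srsy and 18 have no single symbol. The rest were probe sets of Dppa3, Crxos and Nxf3. Identifiers of the 18 run from 10608247 to 10608628 and those of Srsy from 10608209 to 10608596, so these calls may not be separate genes. The Srsy median was 5.38 in Hira-null replicate 2, within the WT values of 5.25 to 5.91, and 2.58 and 2.52 in the other Hira-null arrays.

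The genes that follow Dppa3 among those lower in Hira-null arrays did not pass the test, with limma adjusted p of 0.149 to 0.186. They were chosen from genes whose 3 arrays per line did not overlap. Crxos, a homeobox gene of early embryos, stood at -1.61 (SE 0.17), the X-linked deubiquitinase gene Usp26 at -1.91 (SE 0.22), the X-linked RNA export factor gene Nxf3 at -1.67 (SE 0.18) and the oocyte gene Nlrp14 at -1.40 (SE 0.17). Mpi, the mannose phosphate isomerase gene, went from 8.04 ± 0.09 in WT to 6.15 ± 0.40 in Hira-null arrays. Cpn1, a carboxypeptidase subunit gene, stood at -1.48. The other 5 were Nt5c (-1.16), Map2k6 (-1.16), Fn3krp (-1.07), Prpsap2 (-0.98) and Mks1 (-0.97), and all 5 lie on chromosome 11. Mpi and Usp26 passed with arrayWeights (adjusted p = 0.0416 each, from 0.0416 to 0.604 over the alternatives), and Crxos (0.0343) and Nxf3 (0.0355) without Hira-null replicate 2.

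The 12 named genes with higher values in Hira-null arrays also did not pass (adjusted p = 0.149 to 0.220 with limma), and none lies on chromosome 8 or 11. Efhc2, on chromosome X, had the largest difference among them, from 6.06 ± 0.26 to 7.66 ± 0.33, which is 3.03-fold. The DEAD-box helicase gene D1Pas1 stood at 1.40, the ribosomal protein paralog Rpl10l at 1.32, the RNA-binding protein gene Strbp at 1.13 and Syce1, of the synaptonemal complex, at 0.87. A further Strbp probe set read 0.18, so its probe sets disagree. The histone gene H2bc4 stood at 1.06, Fbxo2 at 1.15 and Tenm4 at 1.05, with 0.31 at a further Tenm4 probe set. Ccdc141 was at 1.01, and its 3 further probe sets gave 0.66 to 1.07. Pepd, a dipeptidase gene, Aoah, an acyloxyacyl hydrolase gene, and Mpc1, of the mitochondrial pyruvate carrier, were at 0.99, 0.96 and 0.85.

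**Figure D1:**
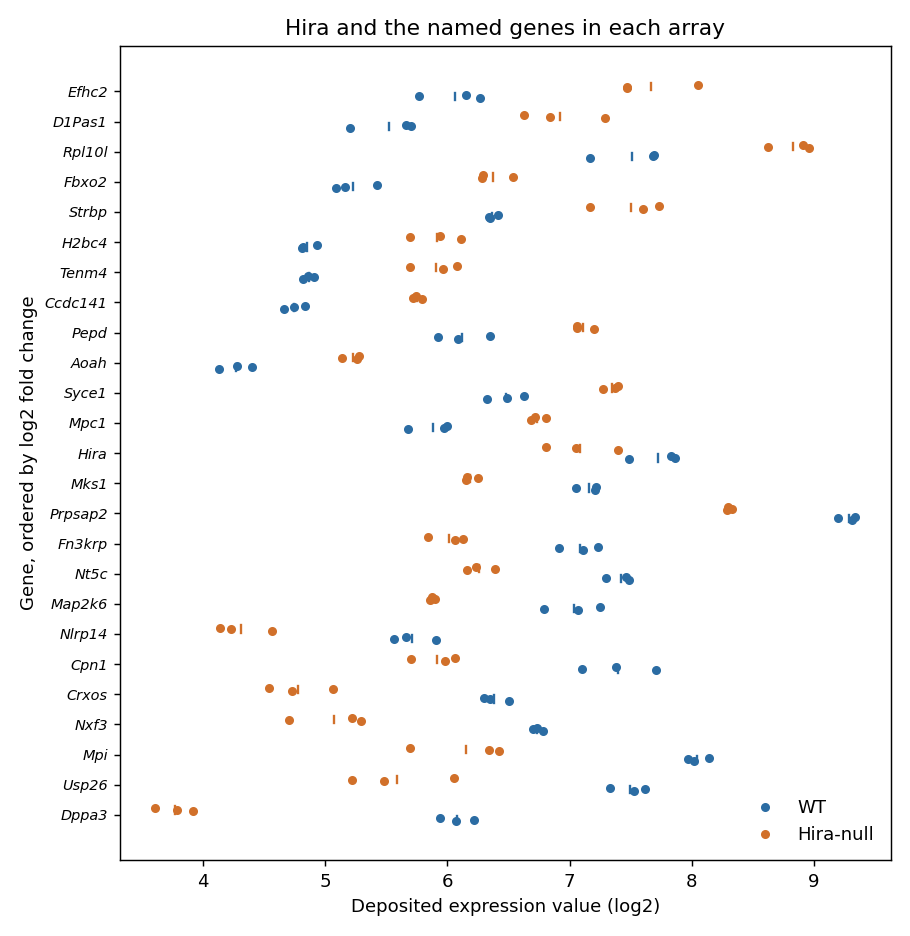
Deposited log2 expression value of Hira and 24 named genes in each of 6 arrays, with WT points in blue, Hira-null points in orange and short bars for the mean of 3 arrays. Dppa3, at the bottom, has the largest separation (6.08 against 3.77). The 24 genes were chosen so that the 3 Hira-null points lie on one side of the 3 WT points, which also holds for Hira.

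Genes on chromosomes 8 and 11 were broadly lower in the Hira-null arrays, and both chromosomes passed the test. On chromosome 8, 82.9% of 809 genes had lower values and the median log2 fold change was -0.27, or 1.21-fold lower. On chromosome 11, 82.5% of 1351 genes had lower values and the median was -0.24, or 1.18-fold lower. The other 18 chromosomes, with Y left out for its 6 measured genes, had medians from 0 to 0.04. The camera test gave adjusted p = 1.9e-21 for chromosome 8 and 3.8e-22 for chromosome 11, and adjusted p = 0.00805 for each with an estimated correlation. The chromosome 8 medians per array were 0.16, 0.11 and 0.10 in WT and -0.14, -0.12 and -0.11 in Hira-null arrays, so all 3 arrays of each line show the difference. For chromosome 11 they were 0.12, 0.12 and 0.10 in WT against -0.14, -0.09 and -0.11. An exact two-sided permutation test of these medians gave p = 0.1, the smallest that 3 arrays against 3 allow. Chromosome assignments are those of the assembly GRCm38.p6.

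**Figure D2:**
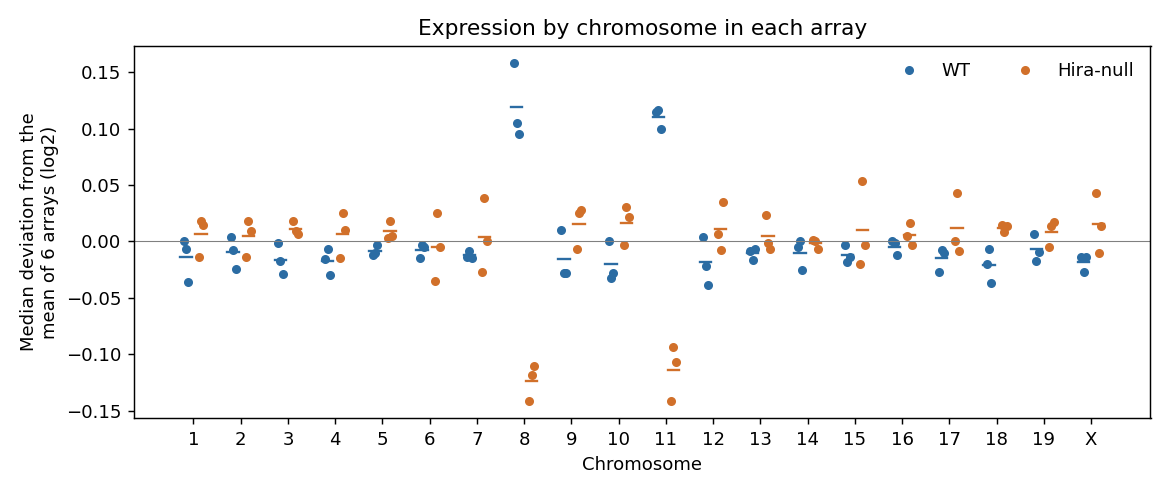
Median deviation of the genes of each chromosome from their mean over 6 arrays (log2), with 1 point per array, WT in blue and Hira-null in orange, and short bars for group means. Chromosomes 8 and 11 separate the lines, with group means of 0.12 and -0.12 on chromosome 8 and 0.11 and -0.11 on chromosome 11.

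The lower values ran along the whole length of both chromosomes. With each chromosome divided into 10 segments of equal gene number, the 20 segments of chromosomes 8 and 11 had medians from -0.35 to -0.15. The 180 segments of the other chromosomes had medians from -0.10 to 0.10. The shift was smaller among genes of low expression. It was -0.08, -0.33 and -0.40 for genes of low, middle and high mean expression on chromosome 8, and -0.09, -0.29 and -0.41 on chromosome 11. Among 954 genes that were lower at an unadjusted p under 0.05, 599 (62.8%) lie on these chromosomes, which hold 14.3% of the genes tested. Among 632 genes that were higher at that level, 12 (1.9%) lie there. On the other chromosomes 355 genes were lower and 620 higher at that level. Genes of one chromosome are not independent, so these counts carry no p-value here.

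**Figure D3:**
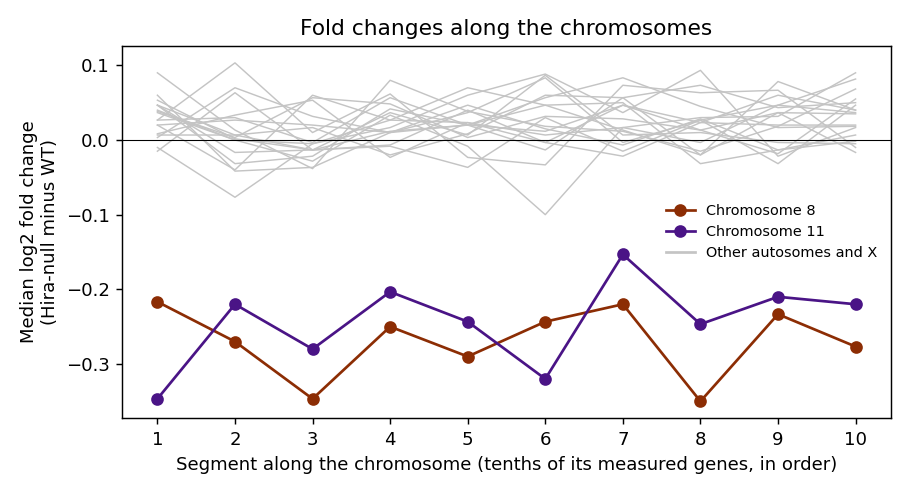
Median log2 fold change (Hira-null minus WT) in 10 consecutive segments of equal gene number along each chromosome, in gene order, with chromosome 8 in brown, chromosome 11 in purple and the other chromosomes except Y in grey. The 20 segments of chromosomes 8 and 11 lie between -0.35 and -0.15, and the others between -0.10 and 0.10.

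Over the 27 gene lists tested, which hold 515 different measured genes, 7 lists passed with the preset correlation. With an estimated correlation or with fry's directional test, 0 passed. The estimated correlation within the 7 lists was 0.31 to 0.80, above the preset value. Groupings of the arrays that mix the lines called 4 to 15 lists with the preset correlation, although they keep part of the line difference. By themselves the 7 calls therefore do not show a line difference. With 1 probe set per gene, no list member passed in limma with adjustment over all genes, Dppa3 being represented by its probe set at adjusted p = 0.0526 rather than the one called (0 of 515, with 68 at an unadjusted p under 0.05), and 12 different genes passed adjusted over the list alone. Cholesterol synthesis genes had 18 of 18 at lower values and a median of -0.42. They passed as a set with the preset correlation only (camera, adjusted p = 0.0033, and adjusted p = 0.864 with an estimated correlation). Examples are Mvd (-0.90) and Dhcr7 (-0.91), which act in the mevalonate and late sterol pathways, Fdps (-0.65) and Stard4 (-0.61), and 0 of 18 passed adjusted over the list alone. The list medians of the lines overlapped, with 0.23, 0.41 and -0.01 in the WT arrays. The median was -0.94 in Hira-null replicate 3, but 0.34 and -0.03 in the other Hira-null arrays. Without that array the median was -0.14 and the call was lost (adjusted p = 0.344), as it was with arrayWeights (median -0.19, adjusted p = 0.0665) and without both this array and WT replicate 1 (median -0.05, adjusted p = 0.443). Without Hira-null replicate 1 the median was -0.75 (adjusted p = 8.2e-08).

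Hypoxia and glycolysis genes had 22 of 24 at lower values and a median of -0.47. Again the set passed with the preset correlation only (camera, adjusted p = 0.0033, and adjusted p = 0.864 with an estimated correlation). The prolyl hydroxylase gene Egln1 (-1.25), the aldolase gene Aldoc (-2.02) and Ankrd37 (-0.76) lie on chromosomes 8 and 11, and the glucose transporter gene Slc2a1 read -0.72. None passed adjusted over the list alone (0 of 24), and the median was -0.31 without the 4 members on those chromosomes. The list medians of the lines overlapped, with 0.46, -0.25 and 0.385 in the WT arrays. Here too the value of Hira-null replicate 3 was apart, at -0.78 against -0.14 and 0.27 in the other Hira-null arrays. Without it the call was lost (median -0.14, adjusted p = 0.202), and without both it and WT replicate 1 the median was 0.04 (adjusted p = 0.616). The call was also lost with arrayWeights (-0.18, adjusted p = 0.0705).

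Markers of primitive and definitive endoderm had 18 of 24 at or below their WT level and a median of -0.28. As a set they passed with the preset correlation only (camera, adjusted p = 0.00903, and adjusted p = 0.864 with an estimated correlation). Cubn, which encodes the endocytic receptor cubilin, was the 1 gene that fell with adjustment over the list alone, at -1.48 (SE 0.24). The laminin gene Lama1 read -0.59 and the transcription factor gene Gata6 -0.55, whereas the apolipoprotein gene Apoe read 1.08. Fibroblast and feeder markers had 15 of 21 at lower values and a median of -0.42. They too passed with the preset correlation only (camera, adjusted p = 0.0208, and adjusted p = 0.864 with an estimated correlation). The members with the smallest p were Thy1 (0.76), Twist2 (-0.40), Vim (-0.61) and Ccn2 (-0.99), and 0 of 21 passed adjusted over the list alone. For both lists the medians per array overlapped between the lines. Hira-null replicate 3 read 0.16 for endoderm and 0.17 for fibroblast markers. WT replicates 2 and 3 read lower, at 0 and -0.005 for endoderm and 0.025 and -0.14 for fibroblast markers. Both lists were highest in WT replicate 1, with medians of 0.41 for endoderm and 0.75 for fibroblast markers. Without this array the medians were -0.18 (adjusted p = 0.0801) and -0.17 (adjusted p = 0.230). Without both it and Hira-null replicate 3 both calls held, at -0.32 and -0.41 (adjusted p = 2.9e-04 each), as they did without Hira-null replicate 3 alone, at -0.39 (adjusted p = 4.7e-05) and -0.57 (adjusted p = 3.1e-04). The endoderm call was also lost without Hira-null replicate 1 (median -0.20, adjusted p = 0.376), and the fibroblast call without Hira-null replicate 1 (-0.35, adjusted p = 0.253) or 2 (-0.38, adjusted p = 0.118), with no filter (adjusted p = 0.137) and with the stricter filter (adjusted p = 0.115).

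Germline genes had 19 of 25 at higher values and a median of 0.30. As a set they passed with the preset correlation only (camera, adjusted p = 0.00569, and adjusted p = 0.864 with an estimated correlation). Adjusted over the list alone, 3 members passed. Mael, of the piRNA pathway, rose by 1.5 (SE 0.33), the germ granule gene Rnf17 rose by 0.89 (SE 0.19) and Tex14, of germ cell intercellular bridges and on chromosome 11, read -0.70 (SE 0.13). Taf7l stood at 1.89 and did not pass. The list median was 0.52 in Hira-null replicate 3 against 0.10 and 0.01 in the other Hira-null arrays, and without that array it was 0.09 (adjusted p = 0.0727). Without both that array and WT replicate 1 the call held (median 0.24, adjusted p = 4.4e-04). The median was larger without Hira-null replicate 1 (0.45, adjusted p = 0.00761) or 2 (0.46, adjusted p = 5.6e-04), with the stricter filter (0.50, adjusted p = 0.0306) and without chromosomes 8 and 11 (0.47, adjusted p = 9.9e-05), and smaller with arrayWeights (0.18, adjusted p = 0.0254). The 2-cell-like state is a rare ES cell state with transcripts of the early embryo. Its genes had 9 of 11 at higher values and a median of 0.40. They passed as a set with the preset correlation only (camera, adjusted p = 0.00569, and adjusted p = 0.864 with an estimated correlation). Tdpoz2 (0.88) and Zfp352 (0.77) passed adjusted over the list alone, and Gm5662 (0.79) and Tmem92 (-0.60) did not. The medians per array were -0.38, 0.03 and -0.43 in WT and 0.37, -0.10 and 0.48 in Hira-null arrays. This call was lost without Hira-null replicate 1 (median 0.42, adjusted p = 0.0601) and with the stricter filter (median 0.52, adjusted p = 0.0802), where the median was not smaller. It was also lost without both WT replicate 1 and Hira-null replicate 3 (median 0.26, adjusted p = 0.136), and held without Hira-null replicate 3 alone (median 0.24, adjusted p = 0.0265).

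Targets of p53 had 14 of 17 at higher values and a median of 0.25. Here too the set passed with the preset correlation only (camera, adjusted p = 0.0278, and adjusted p = 0.864 with an estimated correlation). The apoptosis genes Pmaip1 (0.77), Perp (0.94) and Bbc3 (0.41) and the receptor gene Eda2r (0.69) had the smallest p, and 0 of 17 passed adjusted over the list alone. The medians per array overlapped between the lines, at 0.14, -0.35 and -0.24 in WT and 0.18, -0.37 and 0.56 in Hira-null arrays. This call was lost without WT replicate 2 (adjusted p = 0.241), WT replicate 3 (0.153), Hira-null replicate 1 (0.154) or Hira-null replicate 3 (median 0.09, adjusted p = 0.344), with the stricter filter (0.0547) and with arrayWeights (0.207). It held without both WT replicate 1 and Hira-null replicate 3 (median 0.19, adjusted p = 0.0297), and the median was larger without Hira-null replicate 2 (0.49, adjusted p = 1.4e-05) or WT replicate 1 (0.40, adjusted p = 0.00136). Beside these lists, smooth muscle and keratin transcripts differed between arrays of one line. Acta2 read 9.57 in WT replicate 1 against 7.40 and 7.05 in the other WT arrays, and 8.68 in Hira-null replicate 3 against 6 and 5.49. Krt18 read 9.22 against 7.63 and 7.48, and 10.20 against 7.31 and 7.19, in the same order. Acta2 is a listed marker, and it and Krt18 are named here after their values were seen.

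**Figure D4:**
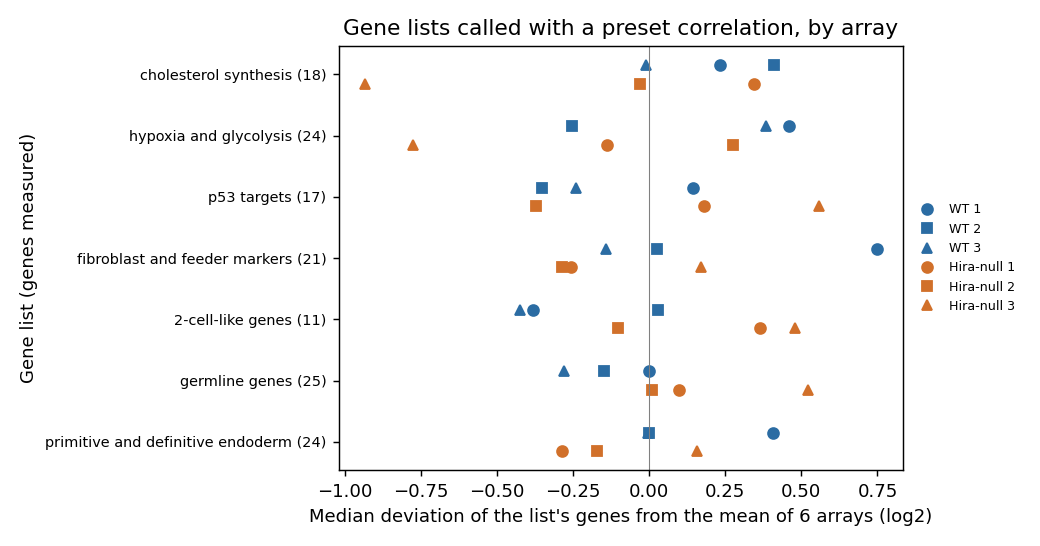
Median deviation of the genes of 7 lists from their mean over 6 arrays (log2), with 1 symbol per array, WT in blue and Hira-null in orange, and the number of measured genes in brackets. Hira-null replicate 3 (orange triangles) stands apart for cholesterol synthesis (-0.94), hypoxia and glycolysis (-0.78) and germline genes (0.52), and WT replicate 1 (blue circles) for fibroblast markers (0.75).

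The core pluripotency genes were expressed at high levels in both lines, with means over all arrays of 11.4 for Pou5f1, 10.1 for Sox2 and 10.9 for Nanog. Their differences were small and did not pass the test. Pou5f1 read 0.27 (SE 0.17), Sox2 -0.11 (SE 0.25) and Nanog 0.05 (SE 0.15). The 32 measured pluripotency genes did not pass as a set (median 0.05, camera adjusted p = 0.473), but fry's test for change in either direction passed (adjusted p = 0.00974). Members went both ways. Adjusted over the list alone, Dppa3 was lower (-1.94) and the T-box gene Tbx3 higher (1.68, SE 0.27), while Klf2, on chromosome 8, was at -0.52 and Klf5 at 0.68 without passing. The set passed as higher without Hira-null replicate 3 (median 0.24, adjusted p = 0.00402) and without both it and WT replicate 1 (0.18, adjusted p = 0.0297), and its median was negative without WT replicate 1 (-0.06) or Hira-null replicate 1 (-0.14). Targets of LIF and STAT3, the cytokine pathway that sustains ES cells, had a median of 0.10 over 15 genes (adjusted p = 0.186). Klf5 (0.68), Klf4 (0.41), Tfcp2l1 (0.61) and Pim3 (0.38) had the smallest p, 5 members were higher at an unadjusted p under 0.05, and 0 passed with either adjustment. This set passed without Hira-null replicate 3 (median 0.15, adjusted p = 0.0155) and without both it and WT replicate 1 (0.10, adjusted p = 0.0244), and its median was negative without WT replicate 2 (-0.0067) or Hira-null replicate 1 (-0.02). For 18 formative and primed epiblast genes the median was 0.08 and the mean -0.06, of opposite sign, and the set did not pass (adjusted p = 0.715). The Nodal pathway antagonists Lefty1 and Lefty2 read -1.34 (SE 0.59) and -1.29 (SE 0.65), Cdh2 -0.43 and Sox4 0.29, with 0 of 18 passing.

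Among chromatin genes, the replication-coupled histone genes had 16 of 20 at lower values and a median of -0.18, without passing as a set (camera, adjusted p = 0.183). H2bc4 was the 1 member that passed adjusted over the list alone, and it was higher (1.06), against -0.40 for H4c6, -0.40 for H2ac4 and -0.34 for H4c4. This list passed as lower without WT replicate 1 (-0.25, adjusted p = 0.0421) or Hira-null replicate 1 (-0.27, adjusted p = 0.0340), and with the genes of chromosomes 8 and 11 left out (adjusted p = 0.0284). Its median was -0.31 in Hira-null replicate 3 against 0.06 and 0.04 in the other Hira-null arrays, and without that array the list stood at 0.01 (adjusted p = 0.905). Of 2 H3.3 genes, 1 had a probe set with a single symbol, which did not pass the filter on low values, so no value is given for either. Other histone chaperones had a median of -0.02 over 16 genes (adjusted p = 0.655), with Asf1b, on chromosome 8, at -0.65, Chaf1b at -0.21, Npm1 at -0.16 and Hat1 at -0.12, and 0 of 16 passed adjusted over the list alone. Polycomb subunits had a median of 0.05 over 26 genes (adjusted p = 0.610). The core subunit gene Suz12, on chromosome 11, read -0.69 and its partner Eed 0.61, with Aebp2 at 0.59 and Phf19 at -0.56, and 0 of 26 passed adjusted over the list alone. The 31 Hox genes had a median of 0.05 (adjusted p = 0.150), with 21 at higher values, and Hoxc13 (0.82), Hoxc12 (0.44), Hoxb9 (0.40) and Hoxd11 (0.31) did not pass. That list passed as higher without Hira-null replicate 1 (0.12, adjusted p = 0.00761), and its median was -0.005 without Hira-null replicate 2.

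Lineage markers other than endoderm did not pass as sets. The neuroectoderm list had a median of -0.01 over 20 genes (adjusted p = 0.281), and passed as lower with the genes of chromosomes 8 and 11 left out (adjusted p = 0.0284). Its median was just above 0 without WT replicate 3 (0.0025) or Hira-null replicate 1 (0.0033). Pax6, an eye and neural regulator, was lower adjusted over the list alone (-1.21, SE 0.18), and Nes (-0.87), Neurod1 (-0.61) and Ncam1 (-0.24) did not pass. Mesendoderm and primitive streak genes had a median of 0.02 over 19 genes (adjusted p = 0.605), with Cdx1 at 0.40, Mesp2 at 0.33, Nodal at 0.32 and Wnt3 at -0.29. Mesoderm, heart and vessel genes had a median of -0.11 over 23 genes (adjusted p = 0.395), with Myl4 at -0.82, Actc1 at -0.51, Myh6 at -0.42 and Tal1 at 0.31. Trophectoderm genes had a median of 0.04 over 15 genes (adjusted p = 0.473), with Id2 at 1.08 (SE 0.66), Gata2 at 0.75, Eomes at 0.38 and Tead4 at 0.27. In these 3 lists 0 members passed adjusted over the list alone. The 30 imprinted genes had a median of 0.00 and a mean of -0.03 (adjusted p = 0.938), with Ndn (-0.54), Nnat (-0.60), Plagl1 (-0.55) and Grb10 (0.61), and 0 of 30 passed adjusted over the list alone. Of 4 measured Y-linked genes, Zfy1 (1.15) and Uty (0.50) were higher adjusted over the list alone, Sry (-0.39) and Eif2s3y (-0.02) did not pass, and nor did the set (median 0.24, adjusted p = 0.357).

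The remaining lists of proliferation, stress, signalling and adhesion genes did not pass as sets. Proliferation genes had 21 of 30 at lower values and a median of -0.14 (adjusted p = 0.178). Aurkb (-0.89), Top2a (-0.48) and Tk1 (-0.55) lie on chromosome 11, and Mybl2 read 0.63. The list passed as lower without Hira-null replicate 1 (-0.32, adjusted p = 0.00927) or Hira-null replicate 2 (-0.32, adjusted p = 0.0230). Its median was -0.52 in Hira-null replicate 3 against 0.19 and 0.11 in the other Hira-null arrays, and without that array the list stood at 0.07 (adjusted p = 0.344). Amino acid and ER stress genes had a median of 0.12 over 22 genes, while the set test pointed down (adjusted p = 0.715), with Xbp1 (-0.83), Phgdh (-0.57), Chac1 (-0.48) and Atf5 (0.28). WNT targets had a median of -0.14 over 14 genes (adjusted p = 0.495), and 0.00 without the 5 members on chromosomes 8 and 11, with Ccnd1 at -0.73, Znrf3 at -0.47, Cdx1 at 0.40 and Bambi at 0.30. FGF and ERK targets had a median of 0.09 over 17 genes (adjusted p = 0.610), with Etv1 at 0.77, Etv4 at 0.57, Etv5 at -0.45 and Ccnd1 at -0.73. Cell adhesion genes had a median of 0.16 over 26 genes (adjusted p = 0.150), with the claudin gene Cldn6 at 1.03, Itgb1, on chromosome 8, at -0.73, Itga5 at 0.62 and Cdh2 at -0.43. This list passed as higher without WT replicate 1 (0.29, adjusted p = 7.0e-04) or Hira-null replicate 2 (0.28, adjusted p = 0.0230). In these 5 lists 0 members passed adjusted over the list alone.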

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

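The fits without WT replicate 1 and Hira-null replicate 3 together, with 1-symbol probe sets alone, and without chromosomes 8 and 11 were chosen after the data were seen. Chromosomes 8 and 11 were called in every setting that tested them, with medians from -0.34 to -0.21 and from -0.33 to -0.19. With their own genes left out, 0 chromosomes were called, by construction. Without the 2 arrays apart, 3 were called, the addition being chromosome 10 at 0.05 (adjusted p = 0.0478).

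The count of called probe sets, 1, all lower and all over 2-fold, was 2 with the stricter filter, with median centring and with 1-symbol probe sets alone, where the other Dppa3 probe set joined. The first and last test fewer probe sets. It was 5 with arrayWeights, where the other Dppa3 probe set, Mpi, Usp26 and an unnamed probe set joined. It was 0 without the 2 arrays apart. Leaving out 1 array gave 0 to 41, with fewer samples in each fit and the 41 reached without Hira-null replicate 2. With the replicate block it was 0 (smallest adjusted p = 0.493), and 2122 probe sets had an unadjusted p under 0.05. No sign of a pairing by number was seen, since same-numbered deviations correlated at -0.34, 0.17 and -0.10 across probe sets and 1 of 6 arrays correlated best with its own number. Deviations within a line are tied to each other, so these few correlations cannot exclude a pairing. The block changed no other call.

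Of 403 values of 24 named genes under the alternatives, 392 stayed on the same side of the threshold, 7 lost and 4 gained a call, and 0 changed sign. Leaving out arrays could not change a sign, because these genes were chosen for groups that did not overlap. Most of the 392 belong to genes that passed neither in the main fit nor in the alternative. Hira stayed between -0.80 and -0.50, with adjusted p from 0.178 to 0.677. The gene lists called, 7, became 4 with the stricter filter, 4 with arrayWeights, and 0 with an estimated correlation or fry's directional test. Among lists called in some setting, leaving out 1 array turned the median of pluripotency (-0.14 to 0.24), LIF and STAT3 targets (-0.0217 to 0.15), neuroectoderm (-0.0783 to 0.0033), Hox genes (-0.005 to 0.12), histone genes (-0.27 to 0.0133) and proliferation (-0.32 to 0.0675). Without the 2 arrays apart, proliferation (0.045) and hypoxia and glycolysis (0.035) also changed sign. The other 13 lists tested passed in no setting, and 32 of their 259 medians under the alternatives had the opposite sign, so no direction is read from them. Where no cause is named, the cause was not tested. How far low signal limits these values could not be judged, because background levels were not analysed here.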

Other observations

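The tests of HIRA loss and of growth stage, and the choice to look at Srsy and at keratin and smooth muscle genes, were made after the results were seen. Srsy, a multicopy gene of the Y chromosome, differed between arrays of the same line. The median over its 19 probe sets was 5.91, 5.81 and 5.25 in the WT arrays and 2.58, 5.38 and 2.52 in Hira-null replicates 1, 2 and 3. Probe sets of a multicopy gene are not independent measurements. Of the listed Y-linked genes, Zfy1 (1.15) and Uty (0.50) were higher adjusted over the list alone, and Eif2s3y (-0.02) and Sry (-0.39) did not pass. Tagln read 8.94 in WT replicate 1 against 7.18 and 6.46 in the other WT arrays, and Krt8 read 10.24 in Hira-null replicate 3 against 8.02 and 7.84.

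Genes of chromosomes 8 and 11 were lower in the Hira-null arrays, and a difference in copy number of the whole chromosomes between the lines is a candidate explanation. It predicts a shift along the entire length, and 20 of 20 segments had a median below -0.1, against 0 of 180 on the other chromosomes. A few strongly changed stretches do not account for it, since without the 2 most shifted segments the median nearer to 0 of the 2 chromosomes was still -0.22, and nor does expression level, since 0 of 10000 random sets matched in size and expression were as low on either chromosome. An action of HIRA loss on these chromosomes cannot be told apart from a difference between clones, because the series holds 1 Hira-null clone, and the data do not show which line would carry the altered number. The shift of -0.40 to -0.41 among highly expressed genes may be set beside -0.58, the log2 of 2 over 3, as for 2 copies against 3. Other splits of the 6 arrays number 10 with the real one, too few for a share under 0.05. The real split called 2 chromosomes and the highest other 3, with 9 splits at 2 or more. Each other split sets 2 arrays of one line and 1 of the other on each side, so part of the line difference remains in it. The chromosome calls of those splits therefore cannot show what would be called without that difference. The largest chromosome median was 0.27 in the real split and 0.12 in the highest other.

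Lower genes outnumbered higher ones at an unadjusted p under 0.05, and by count this excess lay on chromosomes 8 and 11. They hold 4.40 times their share of the genes tested among the lower genes, and on the other chromosomes 620 genes were higher and 355 lower. These chromosomes had been picked out by their lower values in the same fit, so a ratio near 1 was not an open outcome. The ratio describes that shift and does not test it. No biological explanation was tested for this pattern, and HIRA loss, considered above for chromosomes 8 and 11, stays open.

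Hira-null replicate 3 and, less clearly, WT replicate 1 lay apart from the other arrays, and their deviations from their line's mean correlated at 0.44 across probe sets. Compared with the mean of the other 2 arrays of its line, Hira-null replicate 3 had 750 genes over 2-fold away and WT replicate 1 had 257, against 185 in Hira-null replicate 1 and 33 to 120 in the other 3. Hira-null replicate 1 was as far out as WT replicate 1 on principal component 2 (42.7 against -40.7), so the choice of WT replicate 1 as apart is not sharp. Fibroblasts or feeder cells in WT replicate 1 may have contributed, but remain open, since the median difference of Col1a1, Col1a2 and Col3a1 was 1.01 (log2) while Col3a1 alone was 0.04. In Hira-null replicate 3, against the mean of the other Hira-null arrays, the differences of these genes were 1.185, 0.33 and 0.19. Growth stage, which the design text says varied, cannot be told apart from other differences, because 0 arrays have a stage in their labels. Labelling or RNA quality also stays open: the medians of the 2 arrays and the other 4 differed by 0.045, which had been set beforehand to count against it, but that bound was wrong because the deposited normalization equalises the medians of all arrays, which span 0.09.

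The 10 splits are also too few to judge the other counts, and those that mix the lines keep part of the line difference. The real split called 1 probe set and the highest other 0, so 1 split reached the real count. For gene lists the real split called 7 and the highest other 15, and 7 splits reached the real count. The splits with 13 or 15 called lists put WT replicate 1 and Hira-null replicate 3 on one side, which points to a structure of the samples.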
